A study of Homo sapiens with 12 samples.

How the data were processed

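Total RNA of 12 libraries from 22Rv1 and PC3 cells was sequenced paired-end on an Illumina HiSeq instrument, per the labels' protocols. The deposited table holds counts per gene as whole numbers, which were not normalized, and the authors' table has 1 column per library. Per the submitters' processing notes, Bowtie2 2.1.0, RSEM 1.2.15 and edgeR 3.21 were named, with the genome builds hg19, GRCh37 and GRCh38, without saying which tool or build made which values. The table gives Ensembl identifiers and coordinates, and of 58274 identifiers found in GENCODE release 29, 99.97% overlapped the GRCh38 position of the same gene, so coordinates are given in GRCh38. Whether counting used strand is not given in the sources used here, so antisense and overlapping genes cannot be told apart by these counts.

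Columns were assigned to libraries by their names, which match the sample titles, and groups came from the titles. Of 63149 gene entries, 439 carry no gene name and were left out of library sizes and tests. They held 0.136% of counts in OE-NC, 0.192% in OE-FOSB, 0.498% in sh-NC and 0.491% in the libraries labelled sh-FOSB (means of 3). Within each group every pair of libraries differed by more than sampling noise in a chi-square test over genes, so no library was counted as a duplicate. Total counts per library ranged from 13984336 to 18228099. CPM values were computed with TMM-scaled library sizes, except sums over marker genes, control levels set side by side between the lines and limits for a count of 0, which used library totals.

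Each line was fitted separately (3 libraries against 3) in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, scaled by TMM and tested with glmQLFit and glmQLFTest, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The difference between lines used all 12 libraries in 1 fit of 4 group means and the contrast of OE-FOSB minus OE-NC minus the contrast of sh-NC minus labelled sh-FOSB. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation and with fry, and members were adjusted both over all genes and over the list alone. Alternatives used relative log expression (RLE) scaling in edgeR, library totals, and no filter or a minimum of 1 CPM in 3 libraries. Others were the test of DESeq2 1.42.0, limma-voom, replicate number as a block and all 12 libraries in 1 fit. A log2 minimum of 1 was also applied, and each library was left out in turn. Added after the data were seen were the entries with no gene name, a correction for GC content and gene length (known for 96.2% of tested genes in 22Rv1 and 96.8% in PC3), the opposite coding of the knockdown side, the AP-1 list without FOSB, the correlation between lines and 3 further gene lists.

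The groups, tests, the other alternatives, 28 gene lists and the rule for naming genes were set before the data were examined. The rule takes FOSB, IGFBP5 and IGF1, the 10 largest and 10 smallest log2 changes among called genes with a mean log-CPM of at least 1 and no overlap between groups (clone, pseudogene and antisense names replaced by the next), up to 4 members of each list with the smallest adjusted p, any member of the AP-1 and IGF-axis lists, and the 5 smallest p of the difference between lines. Genes named as members of lists were selected from those the rule takes.

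The tests were checked on simulated counts drawn from the means and library sizes of each comparison, with a seeded set of genes changed. In the 22Rv1 simulation (17364 genes) edgeR found 50.7% of genes changed 1.5-fold, 67.2% of those changed 2-fold and 93.9% of those changed 4-fold, with 11 false calls. In the PC3 simulation (16270 genes) it found 10.4%, 58.2% and 86.4%, with 12 false calls. For the difference between lines (19689 genes) it found 5.97%, 43.3% and 54.5%, with 3 false calls. A planted list was called in both lines and 0 of 9 random lists were. Genes were simulated independently of each other, so this check does not bear on lists whose genes vary together. No simulated library was made unlike its group. In the real data replicate 3 labelled sh-FOSB correlated more with sh-NC (0.985) than with its own group (0.973). The shares found for PC3 therefore describe the simulated counts and may not carry over to these libraries.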

Results

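RNA sequencing of 12 libraries covered 22Rv1 cells with FOSB overexpression and PC3 cells labelled as a FOSB knockdown, each with its own vector control. FOSB encodes a FOS-family subunit of the AP-1 transcription factor. 22Rv1 is a human prostate carcinoma line derived from a xenograft, and PC3 is a human prostate carcinoma line from a bone metastasis. The 4 groups held 3 libraries each: 22Rv1 with control vector (OE-NC) or FOSB overexpression (OE-FOSB), and PC3 with control (sh-NC) or FOSB knockdown (sh-FOSB) constructs. The title of the series names FOSB, IGFBP5 and IGF-1 as an axis in prostate cancer growth, so these genes were reported first in each line. Total counts were 13984336 to 14727090 in OE-NC, 14680126 to 16497706 in OE-FOSB, 16023664 to 16896332 in sh-NC and 16195577 to 18228099 in the libraries labelled sh-FOSB. Levels are counts scaled to library size (CPM), given as mean ± SD over n = 3 libraries, and nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples.

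The first comparison asked which transcripts differed in 22Rv1 cells given FOSB. FOSB rose 27.4-fold, from 7.69 ± 1.14 to 212 ± 13.1 CPM, and IGFBP5, a secreted binding protein for insulin-like growth factors, rose 21.9-fold, from 22.8 ± 3.64 to 500 ± 8.11 CPM. IGF1, the growth factor ligand itself, fell from 1.90 ± 0.484 to 0.714 ± 0.125 CPM. The log2 changes were 4.78 (SE 0.0819) for FOSB, 4.45 (SE 0.0715) for IGFBP5 and -1.41 (SE 0.376) for IGF1. Their Benjamini-Hochberg adjusted p-values in the edgeR quasi-likelihood test were 1.78e-22, 6.04e-23 and 0.00365. FOSB (ENSG00000125740) spans positions 45467995 to 45475179 of chromosome 19, IGFBP5 (ENSG00000115461) 216672105 to 216695549 of chromosome 2 and IGF1 (ENSG00000017427) 102395874 to 102481744 of chromosome 12, all in GRCh38 and all protein-coding. These are whole-gene counts, so vector and endogenous FOSB transcripts could not be separated.

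Changes in 22Rv1 were broad. Of 17740 genes tested, 3931 rose and 4228 fell, which is 46.0% of them, and 1192 changed by at least 1 on the log2 scale, 952 upward and 240 downward. Among the largest increases were ATP10A, a phospholipid-flipping ATPase (log2 change 7.12), HHLA2, an immune checkpoint ligand (4.84), RAB7B, a small GTPase of endosomes (4.39), HGF, the ligand of the MET receptor (4.30), CHAC1, a glutathione-degrading enzyme (4.23), CHODL (4.13), the long non-coding RNA ERICD (4.08) and LHX1, a homeobox transcription factor (3.96). HGF went from 2.82 ± 0.470 to 55.5 ± 4.45 CPM and CHAC1 from 2.08 ± 0.541 to 39.4 ± 1.28 CPM. Among the largest decreases were ACHE, acetylcholinesterase (-5.06), FGF12 (-4.16), CD44, the hyaluronan receptor (-3.41), SLC1A2, a glutamate transporter (-3.34), SLC7A5, a transporter of large neutral amino acids (-3.19), SYNPO2 (-2.95), TUBB2A (-2.27), SRPX (-2.20), CORO1A (-2.16) and SDF2L1 (-1.99). ACHE fell from 308 ± 8.76 to 9.26 ± 2.00 CPM, CD44 fell 10.6-fold from 213 ± 10.6 CPM, and SLC7A5 fell from 2841 ± 28.4 to 311 ± 7.36 CPM. TUBB2A, which has the close paralog TUBB2B, stood at 25.7 CPM in OE-NC replicate 3 against 4.35 and 3.28 CPM in the other OE-NC libraries, and its log2 change was -0.73 without that library. The same library held 301.2 CPM summed over 21 markers of pluripotent stem cells, against 0.706 to 1.76 CPM in the other 22Rv1 libraries. These 21 of 26 markers were kept for being under 1 CPM in those other libraries, so low sums there follow from the choice. Without OE-NC replicate 3, 7748 genes passed. The groups did not overlap for 9472 genes, 53.4% of those tested, where chance gives 10%. Scaling by library totals alone shifted the median log2 change of all genes from 0.0146 to 0.123 and the split to 5364 higher and 3013 lower. A fit of all 12 libraries called 4415 genes, 2338 higher and 2077 lower.

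**Figure D1:**
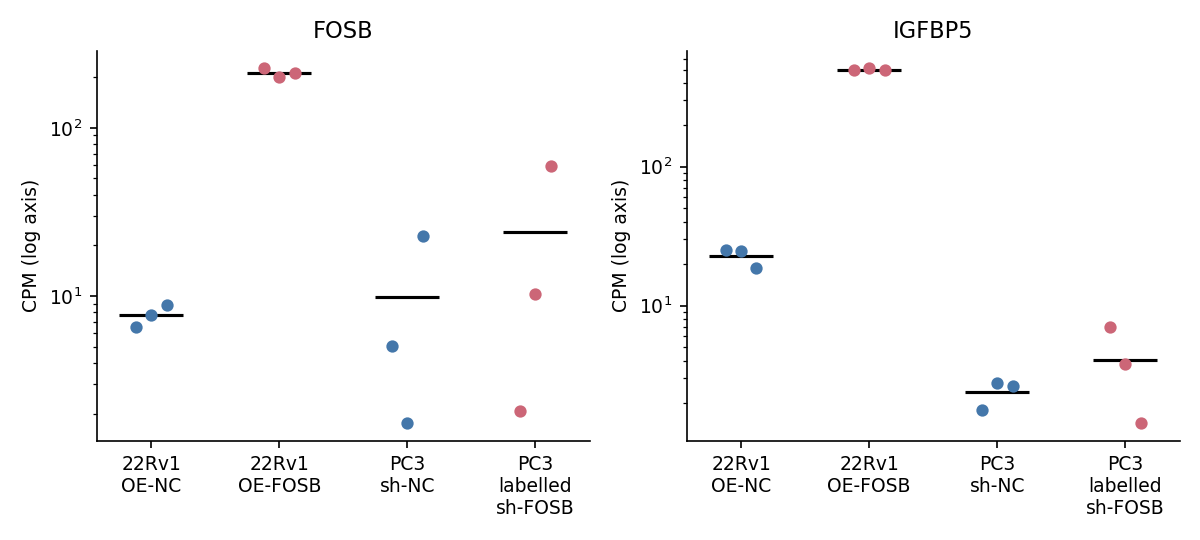
FOSB (left) and IGFBP5 (right) in CPM on a log axis, with each point a library and each bar the mean of a group of 3. In 22Rv1 the OE-FOSB libraries lay above the OE-NC libraries for both genes, whereas the PC3 libraries labelled sh-FOSB overlapped those of sh-NC.

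**Figure D2:**
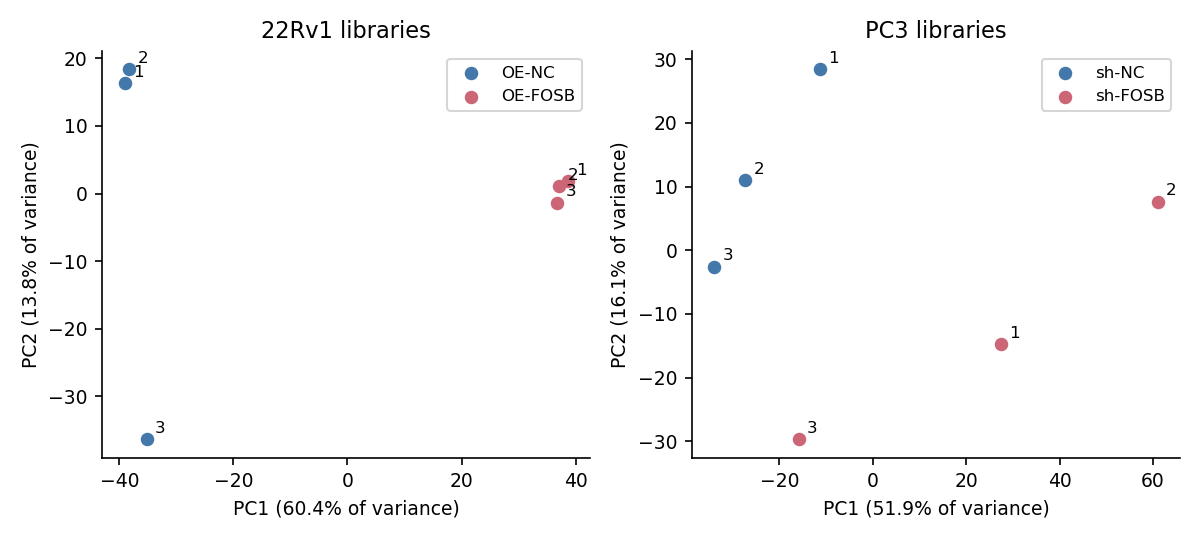
Principal components of log-CPM for the 22Rv1 (left) and PC3 (right) libraries, numbered by replicate, with the share of variance on each axis. The first component (60.4% of variance) separated the 22Rv1 groups, whereas in PC3 (51.9%) replicate 3 labelled sh-FOSB lay among the sh-NC libraries.

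AP-1 subunits and IGF-axis genes were higher in OE-FOSB as groups. Of 16 AP-1 subunits tested, 10 rose and 4 fell (10 and 4 adjusted over the list alone), and 10 were higher and 1 lower under library totals. There JUND (-0.21 with TMM) and BATF3 (-0.77) were among those that lost their calls (edgeR adjusted p = 0.247 and 0.0537). Both also lost them with all 12 libraries in 1 fit. So did JUND by DESeq2, with GC content and length corrected and without OE-FOSB replicate 2. BATF3 did so without OE-NC replicate 1 or OE-FOSB replicate 1 or 3. The list included FOS at 1.71, ATF3 at 1.85, JDP2 at 1.76 and JUN at 1.10 on the log2 scale (camera adjusted p = 1.04e-14). FOSB itself, raised by the construct, was 1 of the 10, and without it 9 of 15 rose and 4 fell, with a median of 0.38 in place of 0.49 (camera adjusted p = 1.74e-07, and adjusted p = 0.0239 with an estimated correlation). Of 23 IGF-axis genes, 13 rose and 2 fell (13 and 2 adjusted over the list alone). They included the binding proteins IGFBP2 (0.97) and IGFBP3 (0.53), the receptors IGF1R (0.73) and INSR (0.62), and the receptor substrates IRS1 (1.31), IRS2 (0.74) and IRS4 (1.52), with a camera adjusted p of 5.86e-12. Immediate-early genes, the first transcripts to respond to growth factors, had 12 higher and 3 lower of 27 (14 and 4 adjusted over the list alone), among them EGR1 (1.92), KLF4 (1.37) and DUSP6 (1.00). Their camera adjusted p was 3.1e-04, and adjusted p = 0.172 with an estimated correlation. PI3K-AKT-FOXO genes had 11 higher and 5 lower of 28 (12 and 5 adjusted over the list alone; camera adjusted p = 2.86e-05). DDIT4 (1.84) and SESN2 (1.34), inhibitors of mTORC1 signalling, TXNIP (1.46), an inhibitor of glucose uptake, and KLHL24 (1.17) rose. The median of that list was 0.11, and -0.01 with 10 higher and 8 lower once GC content and gene length were corrected. Of 29 androgen-responsive genes, 14 rose and 5 fell (14 and 6 adjusted over the list alone), with TMPRSS2 at 2.82 and STEAP2 at 0.77, whereas KLK4 was lower at -0.70. The camera adjusted p of that list was 1.52e-06, and adjusted p = 0.273 with an estimated correlation. Mesenchymal genes had 6 higher and 2 lower of 17 (6 and 2 adjusted over the list alone), including COL5A1 (1.70) and FN1 (0.93), with a camera adjusted p of 0.0304 and adjusted p = 0.415 with an estimated correlation. The median of the mesenchymal list was 0.33, and -0.21 with no filter on low counts, where its call was lost. That call was also lost without OE-NC replicate 1 (median -0.01, camera adjusted p = 0.0987) or 2 (0.11, 0.068) and without OE-FOSB replicate 1 (0.07, 0.0567) or 3 (0.17, 0.0625). Under library totals the higher and lower counts were 15 and 1 for immediate-early, 14 and 3 for PI3K-AKT-FOXO, 16 and 3 for androgen-responsive and 7 and 1 for mesenchymal genes, and for IGF-axis genes they were 11 and 4 with GC content and length corrected. With all 12 libraries in 1 fit, the calls of the immediate-early, PI3K-AKT-FOXO and mesenchymal lists and of FOS (adjusted p = 0.0994) were lost.

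Genes of DNA replication, cholesterol synthesis and glycolysis and MYC targets were lower in OE-FOSB as groups. Of 39 G1/S and DNA replication genes, 36 fell and 1 rose (37 and 1 adjusted over the list alone), including the helicase subunits MCM4 (-0.85) and MCM6 (-0.93), the loading factor CDC6 (-1.09) and the polymerase clamp PCNA (-0.84), with a camera adjusted p of 3.53e-28. Cholesterol synthesis genes fell in 21 of 26 cases and rose in 0 (21 and 1 adjusted over the list alone), with HMGCS1 at -1.25, SQLE at -1.16, ACAT2 at -1.15 and IDI1 at -1.09 (camera adjusted p = 2.53e-26). Among 34 MYC targets 30 fell and 0 rose (31 and 0 adjusted over the list alone), such as SRM, spermidine synthase (-0.95), and NOP56, a nucleolar protein (-0.65), with a camera adjusted p of 1.31e-14. Hypoxia and glycolysis genes had 22 lower and 4 higher of 31 (22 and 4 adjusted over the list alone; camera adjusted p = 1.25e-11), with the glycolytic enzymes PGAM1 (-0.90), HK2 (-0.86), PKM (-0.78) and LDHA (-0.72). Nuclear genes of oxidative phosphorylation fell in 35 of 38 cases and rose in 0 (36 and 0 adjusted over the list alone), including COX6B1 (-0.75) and CYCS (-0.62). Their camera adjusted p was 2.04e-11, and adjusted p = 0.172 with an estimated correlation. G2/M and mitosis genes had 23 lower and 3 higher of 40 (23 and 3 adjusted over the list alone), with AURKB at -0.67, UBE2C at -0.58 and BIRC5 at -0.53. Their camera adjusted p was 2.58e-04, and adjusted p = 0.39 with an estimated correlation. Under library totals G2/M genes had 15 lower and 5 higher and a median of -0.08 in place of -0.19. The G2/M call and those of MCM4, AURKB and BIRC5 were lost with all 12 libraries in 1 fit. In all, 12 of 28 lists were called by camera with a preset correlation, 6 higher and 6 lower, and 7 of these with an estimated correlation.

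Several groups moved in both directions in 22Rv1 and were not called by camera. Genes of the unfolded protein and integrated stress response had 17 higher and 14 lower of 32 (17 and 14 adjusted over the list alone). The endoplasmic reticulum chaperone HSPA5 (-1.93) and its cofactor SDF2L1 fell, whereas SLC7A11, the cystine transporter (2.31), and CHAC1 rose. Among 23 NRF2 targets 6 rose, such as AKR1C3 (2.68), and 11 fell (6 and 11 adjusted over the list alone). Of 33 p53 targets and cell-cycle inhibitors 11 rose and 10 fell (11 and 12 adjusted over the list alone), with CDKN1A, the p21 inhibitor of cyclin-dependent kinases, at -0.85. The higher and lower counts were 8 and 3 of 18 for luminal identity, 4 and 2 of 9 for basal identity, 5 and 3 of 12 for neuroendocrine markers, 8 and 2 of 24 for epithelial genes, 4 and 4 of 13 for AP-1 target proteases and matrix genes, 8 and 4 of 25 for interferon-stimulated genes, 5 and 4 of 17 for NF-kB genes, and 8 and 5 of 23 for TGF-beta response genes. Adjusted over the list alone, these were the same numbers except 5 and 4 for neuroendocrine markers and 8 and 6 for TGF-beta response genes. Ribosomal protein genes had 6 higher and 14 lower of 50, mitochondrially encoded mRNAs 1 and 8 of 13, histones 1 and 2 of 6, fibroblast and endothelial markers 2 and 0 of 5 (LUM, 1.35) and leukocyte markers 1 and 0 of 3, with the same counts adjusted over the list alone. Camera adjusted p-values of these 16 lists ran from 0.112 to 0.924, but luminal identity was called higher under library totals (camera adjusted p = 0.0379). Ribosomal (0.0339) and mitochondrially encoded (0.00431) genes were called lower by camera with no filter on low counts, the latter also without OE-FOSB replicate 2 (0.0284), and the stress response list with all 12 libraries in 1 fit (0.0114, although its median was 0.35). The median and the camera direction differed in sign for the AP-1 target, basal, neuroendocrine, p53, NF-kB, NRF2 and stress response lists. The fry test, unlike camera, called 23 of 28 lists by direction in 22Rv1. Of the 16 lists here it called the luminal, epithelial, interferon-stimulated, TGF-beta, NRF2, fibroblast and endothelial, and leukocyte lists higher. It called the stress response, basal, AP-1 target and mitochondrially encoded lists lower (fry adjusted p = 4.76e-04 to 0.0449 for these calls). The neuroendocrine, p53, NF-kB, ribosomal and histone lists were not called by fry. Under library totals the medians of the p53, NF-kB, neuroendocrine and ribosomal lists turned positive, ribosomal protein genes had 14 higher and 4 lower, mitochondrially encoded mRNAs 4 and 5, epithelial genes 11 and 1, interferon-stimulated genes 10 and 2, TGF-beta response genes 10 and 3, luminal genes 10 and 2, AP-1 target genes 4 and 2, NF-kB genes 6 and 3 and NRF2 targets 6 and 7.

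The second comparison asked which transcripts differed in PC3 cells given the FOSB knockdown construct. FOSB was not lower in the libraries labelled sh-FOSB: its counts were 33, 165 and 1082 there against 82, 29 and 376 in sh-NC, or 23.9 ± 31.1 against 9.81 ± 11.2 CPM. IGFBP5 stood at 4.07 ± 2.79 CPM in the libraries labelled sh-FOSB and at 2.41 ± 0.549 CPM in sh-NC. The log2 differences were 1.29 (SE 1.08) for FOSB and 0.75 (SE 0.496) for IGFBP5, and neither passed the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.546 and 0.451). IGF1 had 0 counts in all 6 libraries, and a floor of 3 counts allows up to 0.165 to 0.188 CPM, for counting error only. Without replicate 3 labelled sh-FOSB the FOSB difference turned to -0.68 (edgeR adjusted p = 0.627) and that of IGFBP5 was 1.15 (edgeR adjusted p = 0.0398). Without replicate 1 labelled sh-FOSB the IGFBP5 difference was 0.10 (edgeR adjusted p = 0.943). FOSB stood at 2.82 without sh-NC replicate 3 (edgeR adjusted p = 0.462). With no filter on low counts FOSB passed as higher at nearly the difference of the main fit (1.28, edgeR adjusted p = 5.27e-09). Its counts overlapped between the groups, so that p-value does not measure the spread of FOSB between these libraries. Because the target gene goes against the label, every direction in PC3 is that of the libraries labelled sh-FOSB against sh-NC.

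In PC3, 3 of 16618 genes passed the test. CCDC141, a coiled-coil protein gene (ENSG00000163492, chromosome 2, 178829757 to 179050137), rose from 19.3 ± 2.38 to 57.7 ± 8.32 CPM in the libraries labelled sh-FOSB. LGALS3BP, a secreted galectin-binding glycoprotein (ENSG00000108679, chromosome 17, 78971238 to 78979947), rose from 31.5 ± 3.41 to 91.0 ± 17.2 CPM. FLNC, the actin crosslinker filamin C (ENSG00000128591, chromosome 7, 128830406 to 128859274), fell from 6.52 ± 0.760 to 1.10 ± 0.286 CPM. The log2 changes were 1.58 (SE 0.151), 1.53 (SE 0.157) and -2.55 (SE 0.272), each with an edgeR Benjamini-Hochberg adjusted p of 0.0327. Genes that did not pass but were among the first of their lists included HPGD, which degrades prostaglandins (2.53, edgeR adjusted p = 0.0838), the histone gene H2BC21 (1.54, 0.0838), NDRG1 (1.84, 0.124), the insulin receptor INSR (0.69, 0.125) and the mitotic kinase AURKA (-0.94, 0.168). Each of these 5 genes passed by DESeq2, with no filter on low counts, with all 12 libraries in 1 fit and without replicate 3 labelled sh-FOSB. At an unadjusted p under 0.05 there were 2846 genes. The groups did not overlap for 3815 genes, 23.0% of those tested, where chance gives 10%. DESeq2 called 627 genes, limma-voom 0, edgeR with no filter on low counts 1389, a fit of all 12 libraries 1173 and a fit with replicate number as a block 119. The count was 2682 without replicate 3 labelled sh-FOSB, 13 without its replicate 2, and 0 without its replicate 1 or without any single sh-NC library. Replicate 3 labelled sh-FOSB correlated at 0.985 with the sh-NC libraries and at 0.973 with its own group.

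Cell-cycle genes were lower and histone, ribosomal and androgen-responsive genes higher in the libraries labelled sh-FOSB by camera with a preset correlation, although 0 members of any list passed the gene test. All of these calls were lost with the correlation estimated: the G1/S and G2/M lists had adjusted p = 0.637 with an estimated correlation, the histones 0.592, the ribosomal list 0.638 and the androgen-responsive genes 0.421. The medians were -0.70 over 39 G1/S genes (camera adjusted p = 2.55e-13, and adjusted p = 0.637 with an estimated correlation), such as RFC4 (-0.64), and -0.69 over 39 G2/M genes (2.61e-17 and 0.637), such as UBE2C (-0.69) and AURKA. MYC targets had a median of -0.18 over 34 genes (camera adjusted p = 8.17e-04) and nuclear oxidative phosphorylation genes one of -0.17 over 38 (0.00209), and they had adjusted p = 0.637 and 0.638 with an estimated correlation. On the higher side stood 8 replication-dependent histones (median 1.33, camera adjusted p = 9.22e-11), 50 ribosomal protein genes (0.31, 8.83e-06), 13 mitochondrially encoded mRNAs (0.30, 8.17e-04), 22 androgen-responsive genes (0.34, 8.17e-04), such as HPGD, 32 hypoxia and glycolysis genes (0.31, 0.00126), such as NDRG1, and 29 PI3K-AKT-FOXO genes (0.10, 0.0317), such as KLHL24 (1.51). Of 28 lists 10 were called, and 0 with an estimated correlation, where the histone list had adjusted p = 0.592 with an estimated correlation, the androgen-responsive list 0.421, the ribosomal list 0.638 and the mitochondrial, hypoxia and PI3K-AKT-FOXO lists 0.637. Adjusted over the list alone, 7 histones, 5 androgen-responsive genes, 9 hypoxia genes and 6 PI3K-AKT-FOXO genes were higher, and 0 members of the other 6 called lists passed. The fry test called 0 lists. The ribosomal call was lost without replicate 2 labelled sh-FOSB (median 0.08, camera adjusted p = 0.169), and without its replicate 1 those of the hypoxia (0.15, 0.053), oxidative phosphorylation (-0.10, 0.0545) and PI3K-AKT-FOXO lists (0.08, 0.0776) were lost. The PI3K-AKT-FOXO call was also lost without sh-NC replicate 1 (median 0.15, camera adjusted p = 0.075) or 2 (0.11, 0.165).

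The other 18 lists were not called in PC3. AP-1 subunits had a median of 0.21 over 17 genes (camera adjusted p = 0.0754), with FOS at 1.56 (edgeR adjusted p = 0.407) and 3 members higher adjusted over the list alone. IGF-axis genes had a median of 0.30 over 21 genes (camera adjusted p = 0.0533), and INSR and IRS2 (0.96) were the 2 members higher adjusted over the list alone. Counts adjusted over the list alone were 6 higher and 4 lower for AP-1 target proteases and matrix genes, 5 and 1 for p53 targets, 3 and 2 for basal identity, 1 and 2 for NRF2 targets, 3 and 0 for NF-kB genes, and 2 and 0 for mesenchymal and for interferon-stimulated genes. They were 1 and 0 for the immediate-early, TGF-beta, stress response, fibroblast and endothelial, and leukocyte lists, and 0 and 0 for the luminal, neuroendocrine, epithelial and cholesterol lists. Camera adjusted p-values of the 18 lists ran from 0.0533 to 0.866. Under alternatives 7 of these lists were called higher by camera with a preset correlation. In the main fit the IGF-axis, AP-1 and luminal lists each had adjusted p = 0.637 with an estimated correlation. IGF-axis genes were called under library totals (camera adjusted p = 0.0474), with all 12 libraries in 1 fit (0.0412) and without sh-NC replicate 3 (0.00973) or replicate 2 (0.0138) or 3 (0.0151) labelled sh-FOSB. AP-1 subunits were called with no filter on low counts (camera adjusted p = 0.024), with replicate number as a block (0.0426) and without sh-NC replicate 3 (0.00406) or replicate 2 labelled sh-FOSB (0.0483). Luminal genes were called with the block (camera adjusted p = 0.0149) and without sh-NC replicate 2 (0.0459) or replicate 3 labelled sh-FOSB (0.00443), and immediate-early genes without sh-NC replicate 3 (0.0121) or replicate 2 labelled sh-FOSB (0.0415). Without replicate 1, 2 or 3 labelled sh-FOSB, respectively, interferon-stimulated (camera adjusted p = 0.0271), cholesterol (4.14e-05) and stress response genes (0.00125) were called. Median and camera direction differed in sign for the basal, neuroendocrine and mesenchymal lists.

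**Figure D3:**
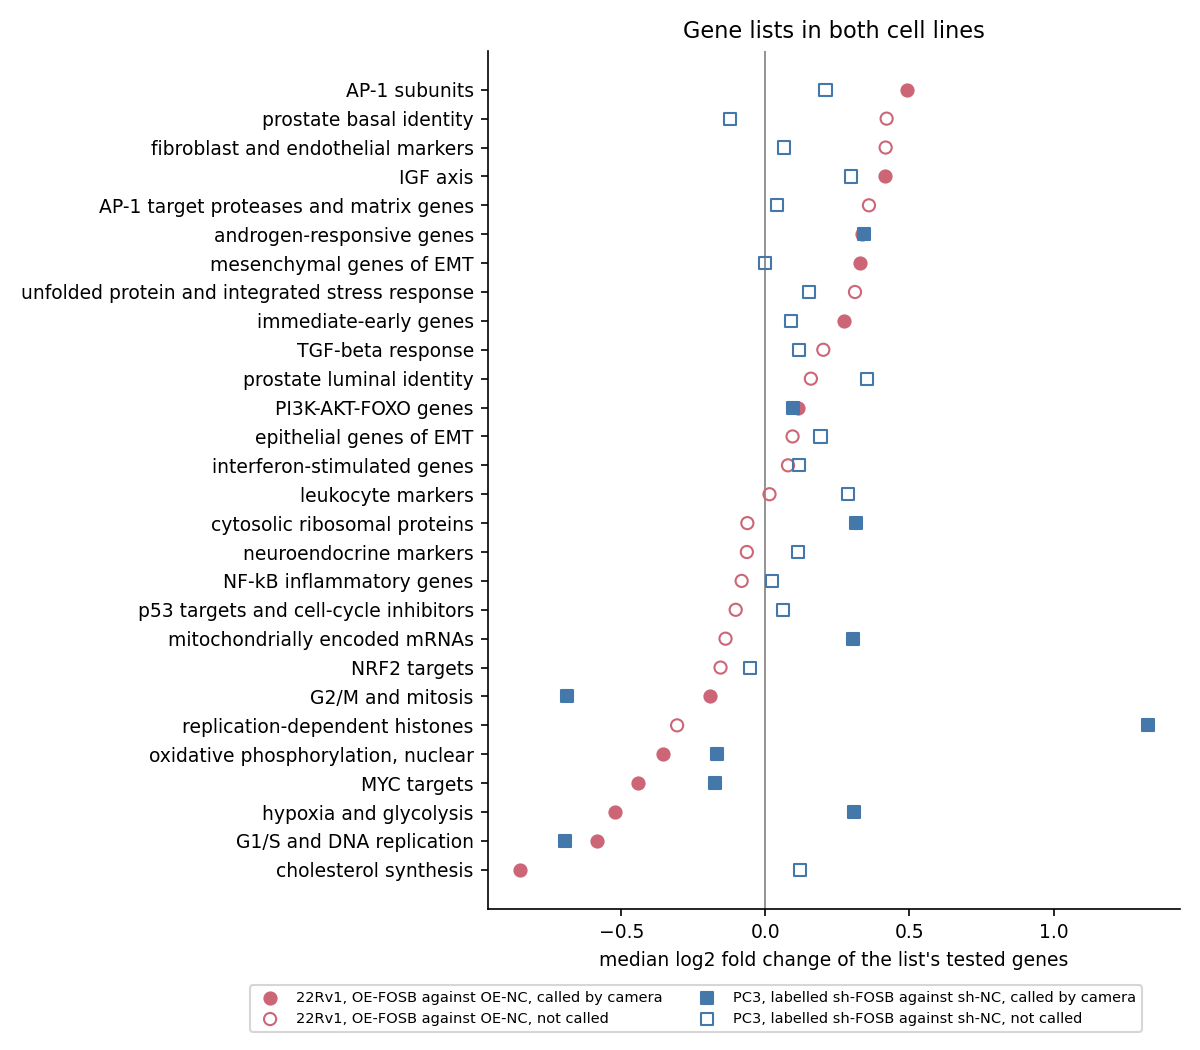
Median log2 fold change of the tested genes of each of 28 lists in 22Rv1 (circles, OE-FOSB against OE-NC) and PC3 (squares, libraries labelled sh-FOSB against sh-NC), filled where camera with a preset correlation called the list. Cholesterol synthesis was lowest in 22Rv1 at -0.85, and histones were highest in PC3 at 1.33.

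The third comparison asked whether the effect coded as higher minus lower FOSB, by the labels, differed between the lines. 22Rv1 had only the overexpression and PC3 only the knockdown construct, so line and manipulation cannot be told apart in it. CA12, a membrane carbonic anhydrase, rose in 22Rv1 from 16.1 to 87.8 CPM and stood at 204 CPM in sh-NC and 203 CPM in the libraries labelled sh-FOSB. HSPA5 fell from 2522 to 663 CPM in 22Rv1 and stood at 772 and 697 CPM in PC3. INHBB, an inhibin and activin subunit, rose from 4.21 to 46.7 CPM and stood at 3.61 and 6.83 CPM in PC3. SLC7A5 fell from 2841 to 311 CPM and stood at 550 and 523 CPM in PC3, and ZNF503, a zinc finger transcriptional repressor, rose from 11.1 to 62.0 CPM and stood at 783 and 979 CPM in PC3. The log2 differences between the effects were 2.47 (SE 0.143) for CA12, -2.04 (SE 0.122) for HSPA5, 4.42 (SE 0.270) for INHBB, -3.23 (SE 0.198) for SLC7A5 and 2.84 (SE 0.176) for ZNF503, each with an adjusted p of 9.69e-07 in the edgeR quasi-likelihood interaction test with Benjamini-Hochberg adjustment. IGFBP5 differed by 5.22 (SE 0.482, edgeR adjusted p = 2.67e-05) and FOSB by 6.11 (SE 1.24, edgeR adjusted p = 0.00368). Of 20109 genes tested 4490 differed, 2315 with a higher and 2175 with a lower effect in 22Rv1, and 3842 of them had changed in 22Rv1 with the same sign. That fit took a shared dispersion for each gene over both lines. The common coefficient of variation between replicates was 0.0624 in 22Rv1 and 0.179 in PC3, so the spread in PC3 can be understated. By line, a fit of all 12 libraries called 1173 genes in PC3 and 4415 in 22Rv1, against 3 and 8159 in separate fits. FOSB was not lower in the libraries labelled sh-FOSB, so the coding rests on the labels, and 1329 genes differed when the PC3 side was taken as labelled sh-FOSB minus sh-NC, of which 716 were among the 4490 and 1176 had changed in 22Rv1 with the same sign. In that coding FOSB did not pass (3.52, edgeR adjusted p = 0.107), INHBB stood at 2.59, CA12 at 2.49, HSPA5 at -1.74, SLC7A5 at -3.08, ZNF503 at 2.20 and IGFBP5 at 3.76.

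Genes changed in opposite directions in OE-FOSB and in the libraries labelled sh-FOSB were sought among 14643 genes tested in both lines. By edgeR 0 genes were mirrored, and LGALS3BP passed in both with the same sign (0.72 in 22Rv1, 1.53 in PC3). Among the genes tested in both lines, only 1 was called higher and 1 lower in PC3. Independent lists would then give 0.49 mirrored genes, so the count of 0 cannot show that mirrored genes are absent. At an unadjusted p under 0.05 in PC3, 276 genes were mirrored against 611.4 for independent lists, and 1229 changed in the same direction against 597.1 (Fisher's exact test across genes, 3.66e-146). DESeq2 found 50 mirrored genes and 235 with the same sign, limma-voom 0 and 0, edgeR with no filter on low counts 105 and 622, a fit of all 12 libraries 60 and 378, and a fit with replicate number as a block 11 and 39. The log2 changes of the lines correlated across genes at r = 0.30 (rho = 0.33), and at 0.04 with no filter and 0.15 with all 12 libraries in 1 fit. Genes are not independent replicates. Without replicate 3 labelled sh-FOSB 207 genes were mirrored and 1307 had the same sign, and without OE-NC replicate 3 there was 1 of each.

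**Figure D4:**
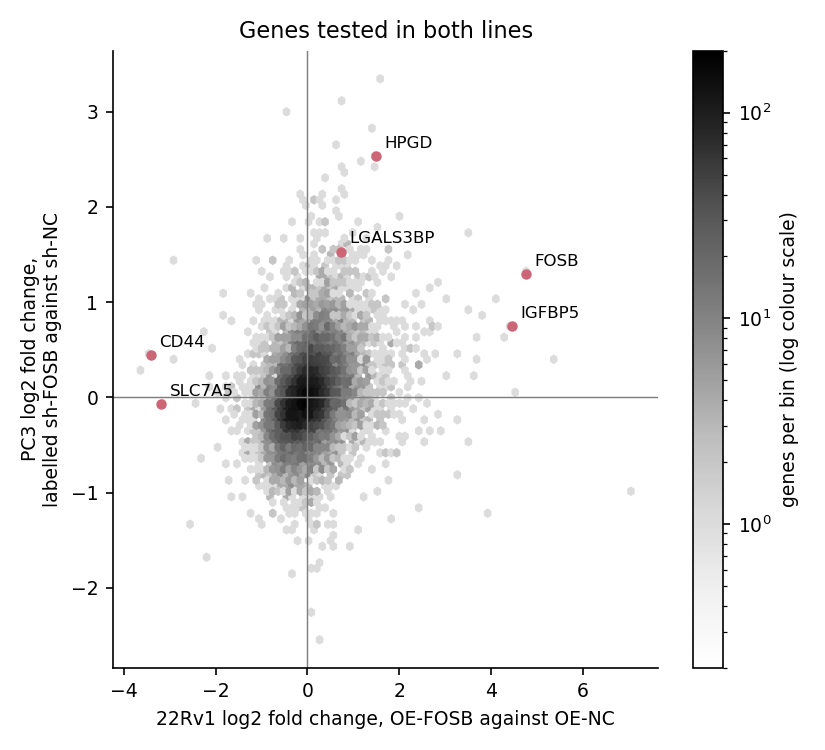
Log2 fold changes of genes tested in both lines, 22Rv1 OE-FOSB against OE-NC on the horizontal axis and PC3 labelled sh-FOSB against sh-NC on the vertical axis, with grey bins coloured by genes per bin on a log scale. The cloud leans to the same direction in both lines (r = 0.30 across genes), and FOSB and IGFBP5 lie far to the right at 4.78 and 4.45.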

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

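The tests of stem cell markers, of immediate-early activity and label exchange in PC3, and of other splits of the libraries for gene counts were chosen only after the results were seen, as was that of a state among PC3 libraries, whereas those of hidden repression and the others of the shared direction of change were set before. For hidden repression and for a change that follows FOSB in PC3, the rules applied allow for the spread between libraries and differ from those set before. The earlier rules counted against hidden repression if relative FOSB was on average as high or higher in the libraries labelled sh-FOSB. They counted against a change that follows FOSB if r was under a fixed low limit. By them the values, 0.7226 and r = -0.115, would have counted against both. 

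The effect coded by the labels as higher minus lower FOSB differed between the lines for 4490 genes by an interaction test. Line and manipulation cannot be told apart in this test, which also shared dispersions between lines of unequal spread. On the log2 scale the difference was 2.468 for CA12, -2.041 for HSPA5, 4.417 for INHBB, -3.23 for SLC7A5, 2.842 for ZNF503, 6.108 for FOSB and 5.216 for IGFBP5. Of 100 drawn splits within the lines, 1, the real one, called as many genes (highest other 4452). The 91 splits that mixed the 22Rv1 groups called at most 1 gene, so they bear on the change in 22Rv1 and not on the difference between lines. The 9 that kept the 22Rv1 groups whole called at least 676, and 9 are too few for a share under 0.05. For 22Rv1 alone 1 of 10 splits called as many genes (real 8159, highest other 0) and for PC3 alone 1 of 10 (real 3, highest other 0), and 10 splits are too few for a share under 0.05. Gene entries with no name, left out of all tests, took 0.1924% of counts in OE-FOSB against 0.136% in OE-NC, a difference of 0.0567 with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow.

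FOSB was not lower in the libraries labelled sh-FOSB. An exchange of some libraries between the PC3 groups was argued against, since each sh-NC library correlated more with its own group than with the other, by at least 0.01004, although replicate 3 labelled sh-FOSB correlated less with its own group, by -0.012, and a single wrong label stays open. An exchange of the whole groups leaves those correlations as they are and cannot be told apart, since the FOSB difference of 1.291 (SE 1.08) did not pass the test. With no filter on low counts that difference was 1.28 and passed (edgeR adjusted p = 5.27e-09). The counts overlapped between the groups, so that p-value does not measure their spread. The difference was -0.68 without replicate 3 labelled sh-FOSB. Neither a construct that did not lower the transcript nor any other biological explanation was tested. Over the 6 libraries FOSB followed the mean of the other immediate-early genes (r = 0.949, exact permutation p = 0.00278, adjusted 0.00556 over 2 relations; rho = 0.943, p = 0.0167, adjusted 0.0334; r = 0.764 without the 2 farthest libraries), so differing immediate-early activity is a candidate explanation. Whether such activity hid a repression cannot be told apart with 3 libraries per group: FOSB relative to those genes was 0.7226 higher on the log2 scale in the libraries labelled sh-FOSB (exact permutation p = 0.7, where 0.1 is the smallest possible).

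Transcripts of pluripotent stem cells stood out in OE-NC replicate 3. Of 26 markers written down, 21 were under 1 CPM in the other 5 22Rv1 libraries, and 20 of these were higher in this library than in each of them, led by LIN28A at 78.3, ESRG at 34.3, CLDN6 at 27.9 and LEFTY2 at 26.6 CPM. Carry-over from the PC3 libraries was argued against, since the markers summed to at most 3.223 CPM there and to 301.2 CPM here, and so was an exchange with an OE-FOSB library, since this library correlated more with its own group by 0.01569. RNA or reads of pluripotent stem cells in that library may account for the pattern, and no biological explanation was tested.

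Changes in the same direction in both lines, r = 0.30 across genes, stood beside labels of a gain in 22Rv1 and a loss in PC3. A bias of GC content or gene length was argued against, since r was 0.304 with those trends removed, whereas a change that follows FOSB in PC3 cannot be told apart with 6 libraries: the score of 22Rv1 genes had r = -0.115 with FOSB (exact permutation p = 0.815; rho = 0.143, p = 0.803; r = -0.322 without the 2 farthest). A state that varies among PC3 libraries whatever their label cannot be told apart either, since the 22Rv1 changes correlated at most at 0.1199 in size with the difference between 2 sh-NC libraries, and replicate 3 labelled sh-FOSB may carry a wrong label (a test set before, r = 0.217 for replicates 2 and 3 labelled sh-FOSB, was dropped because that pair was picked by its correlation to sh-NC). The difference between replicates 1 and 3 labelled sh-FOSB had r = 0.22, and that between replicates 1 and 2 had r = -0.0829. Of 10 splits of the PC3 libraries 2 gave a correlation as large (real 0.30, highest other 0.3019), and 10 splits are too few for a share under 0.05, while an effect of the knockdown construct itself and an exchange of the whole PC3 groups stay open.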

How the results depend on the processing

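Tests added after the results were seen were those with unnamed gene entries kept, GC content and length corrected, the opposite coding of the knockdown side, the AP-1 list without FOSB, the correlation between lines and the 3 added gene lists; the cause of each change below was not tested except where fewer genes or libraries entered. In 22Rv1 the count of changed genes was 4415 with all 12 libraries in 1 fit and 1192 with a log2 minimum of 1, and 7286 to 7748 with a library left out. In PC3 it was 1389 with no filter on low counts, 627 by DESeq2, 0 by limma-voom, 1173 with all 12 libraries in 1 fit, 5 with unnamed entries kept and 0 to 2682 with a library left out. For the difference between lines it was 1748 with a log2 minimum of 1, 1329 with the knockdown side coded the other way and 3327 to 6448 with a library left out. Mirrored genes numbered 105 with no filter, 50 by DESeq2, 60 with all 12 libraries and 0 to 207 with a library left out. FOSB in PC3 was 1.28 with no filter, past the threshold (edgeR adjusted p = 5.27e-09, range over its alternatives up to 0.808) although its counts overlapped between the groups. It was -0.68 to 2.82 with a library left out, turning to -0.68 without replicate 3 labelled sh-FOSB. IGFBP5 in PC3 was 0.10 to 1.15 with a library left out, and passed without replicate 3 labelled sh-FOSB (edgeR adjusted p = 0.0398). In 22Rv1 FOSB was 4.67 to 4.89 and IGFBP5 4.32 to 4.53 with a library left out, and both kept their direction and call under every alternative run. Lists called with an estimated correlation numbered 7 in 22Rv1 and 0 in PC3, and with a library left out 11 to 13 and 8 to 13.

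Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.0136, 0.000727 and 0.0287 in 22Rv1 and at -0.0322, -0.0798 and 0.224 in PC3. With replicate number as a block, 8296 genes were called in 22Rv1, 119 in PC3, 4299 between lines, and 11 were mirrored, with 12 lists called in each line. Leaving out FOSB and IGFBP5, given above, of 1232 values of named 22Rv1 genes under alternatives 1217 kept direction and call and 15 lost the call, and of 224 in PC3 165 kept both, 44 passed newly and 15 lost the call. All 132 values of named differences between lines kept both, leaving out 1 DESeq2 value with no adjusted p and the opposite coding of the knockdown side, under which 6 of the 7 kept both and FOSB lost its call (3.52, edgeR adjusted p = 0.107). For the called lists and the 3 added ones, 187 of 201 values in 22Rv1 kept both and 14 lost the call, and 149 of 175 in PC3 kept both, 9 of added lists passed newly and 17 lost the call. Of the other fixed lists, 4 passed newly in 22Rv1 (5 values) and 7 in PC3 (17 values). CCDC141, LGALS3BP and FLNC in PC3 lost their calls under limma-voom (adjusted p = 0.0516 each) and without sh-NC replicate 1, 2 or 3 or replicate 1 labelled sh-FOSB. The correlation between lines moved in 2 of 22 settings, to 0.04 with no filter and 0.15 with all 12 libraries. Depth limits low genes: the 0 counts of IGF1 in PC3 allow levels of up to 0.165 to 0.188 CPM, for counting error only.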

Other observations

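The 3 gene lists of chaperones and ATF4 targets were written, and their tests chosen, only after the values were seen. What follows thus describes genes chosen for the pattern, and no test of them as groups is given for 22Rv1. The group tests given for PC3 carry the same limit, since the log2 changes of the lines correlated across genes (r = 0.30). Their p-values are descriptive and are no independent support.

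Chaperones fell in 22Rv1 with FOSB overexpression while targets of ATF4, the transcription factor of the integrated stress response, mostly rose. All 15 endoplasmic reticulum chaperones and folding enzymes tested fell (15 adjusted over the list alone; median -0.88), including HSPA5 (-1.93), DNAJB11 (-1.42) and MANF (-1.30). All 16 heat-shock chaperones fell (16 adjusted over the list alone, median -0.97), including HSPH1 (-1.35), HSPA8 (-1.29) and HSP90AA1 (-1.24). That list was written as cytosolic but also holds the mitochondrial chaperonins HSPD1 (-0.45) and HSPE1 (-0.91). Of 17 ATF4 targets 14 rose and 2 fell (14 and 2 adjusted over the list alone; median 1.04), with ASNS, asparagine synthetase, at 2.79, TRIB3 at 1.47 and PSAT1 at 1.04, whereas the amino acid transporter subunits SLC7A5 (-3.19) and SLC3A2 (-0.97) fell. The lists fixed earlier held 10, 2 and 15 of these members, and the fixed stress response list, with 17 higher and 14 lower, was not called. Under library totals the counts were 14 of 15 and 15 of 16 lower, and 15 of 17 higher.

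In PC3, 0 members of these lists passed the edgeR test with the filter on low counts and all 6 libraries, in the libraries labelled sh-FOSB against sh-NC. With no filter 8 heat-shock and 2 endoplasmic reticulum chaperones were lower and 4 ATF4 targets higher, and with all 12 libraries in 1 fit these counts were 9, 2 and 1. The heat-shock list had a median of -0.44 (camera adjusted p = 8.31e-11, adjusted p = 0.185 with an estimated correlation), with 9 members lower adjusted over the list alone. The endoplasmic reticulum list had a camera adjusted p of 0.109 and adjusted p = 0.605 with an estimated correlation, and a camera adjusted p of 0.0438 with no filter on low counts and 0.0411 without sh-NC replicate 3. The ATF4 list had a median of 0.39, a camera adjusted p of 0.0509 and adjusted p = 0.61 with an estimated correlation. It was called under library totals (0.0454), no filter (0.00609), replicate number as a block (0.0244), all 12 libraries in 1 fit (0.0284), GC content and length corrected (0.0464), without sh-NC replicate 3 (0.0328) and without replicate 3 labelled sh-FOSB (9.03e-07, with 8 members higher and 1 lower).

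Control libraries of the lines differed in marker genes, chosen after their values were seen and described without a test. IGFBP3 stood at 587 ± 14.5 CPM in OE-NC and 3.74 ± 0.256 CPM in sh-NC (SD, n = 3). The AP-1 subunit FOSL1 stood at 0.557 ± 0.267 and 205 ± 39.8 CPM. VIM, vimentin, stood at 7.80 ± 7.74 and 423 ± 30.5 CPM, and OE-NC replicate 3, which held stem cell transcripts, carried the first mean, with 17.4 CPM after TMM scaling against 3.90 and 3.06 CPM in the other OE-NC libraries. HOXB13 at 303 ± 10.5 and 837 ± 74.0 CPM and FOXA1 at 371 ± 15.4 and 322 ± 13.9 CPM were present in both. Long non-coding RNAs took 1.80% of counts in OE-NC and 2.27% in OE-FOSB, with a difference of 0.472 percentage points, and detected genes numbered 27573 and 29344 on average, each with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Long non-coding RNAs took 1.47% in sh-NC and 1.80% in the libraries labelled sh-FOSB. Mitochondrial genes took 5.24% and 6.48% there, each difference with an exact permutation p of 0.2.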
